A study of Mus musculus with 4 samples.

How the data were processed

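The analysis covered 4 arrays of mouse nail matrix, 2 of microdissected distal matrix and 2 of microdissected proximal matrix, from animals aged 8 weeks. Total RNA was extracted with Trizol and labelled with a kit for amplification from the 3' end, per the labels' protocols. The labels number the arrays of each region 1 and 2. They do not say whether these came from separate animals, litters or pools, so the p-values measure only the spread between these samples, which may be technical.

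The deposited value table holds linear intensity values per probe set, scaled by the authors by a method not given in the sources used here. The mean intensity after trimming 2% at each end was 150.0 on every array, computed over all probe sets. The second file is a fold change list: per the file headers it came from a guided workflow on Affymetrix Mouse430_2 arrays, kept probe sets at a fold cut-off of 1.99 with the distal matrix as control, and put no effective limit on p. Its fold carries no sign and sets the higher region over the lower, with the direction in a column of its own. Its group columns are the authors' log2 values, whose absolute difference equals log2 of the fold. How those log2 values were summarised and normalised is not given in the sources used here. The list holds 1437 probe sets, 2 of them controls, and 0 columns of either file were left without a sample or comparison.

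Gene names come from the authors' list alone. Of its 1435 probe sets for genes, 1234 have 1 gene symbol, 50 have several and 151 have none; probe sets outside it carry no name here. The 1234 stand for 1133 genes, of which 1060 were matched by gene identifier to a RefSeq gene table of assembly GRCm38.p6, and 143 symbols were updated through it. Coordinates were not used. Gene groups could therefore be examined only among probe sets the authors had chosen for fold change on these arrays. Wls, Axin2, Wnt6, Wnt7b, Wnt10a, Lgr6, Krt14, Krt5, Krt10, Mki67, Msx2, Foxn1 and Fgf2, which were to be named whatever their result, were not among the listed genes and are not analysed here.

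Intensities below 1 were raised to 1 and log2 was taken. The 64 control probe sets were left out. The other 45037 were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of variance with intensity), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene was represented by its listed probe set with the highest mean over all 4 arrays. Differences are distal minus proximal on the log2 scale, with limma's standard error. A probe set that was at or below the highest of 27 control probe sets for Bacillus subtilis genes on both arrays of a region was taken as not above background there, and its fold is given as a bound against that control. This rule was chosen after the values were seen. The highest such control had intensities of 58.0 and 81.0 on the distal and 96.8 and 45.4 on the proximal arrays, and 43.0%, 35.4%, 33.6% and 47.5% of probe sets lay above it. Intensity ratios of the 3' to the 5' control probe set of Gapdh, a sign of RNA length, were 9.40 and 6.73 on the distal and 7.73 and 8.15 on the proximal arrays. Those of beta-actin went the other way, at 0.52 and 0.59 on the distal and 0.56 and 0.64 on the proximal arrays.

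The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 10 genes with the largest difference in each direction among those that passed, did not overlap between regions and had a higher-group mean above the median. Places left over went to the smallest p-values and are given as not passing. It added up to 3 genes per direction from each list of biology, up to 2 by level and 2 by p from each list of other cells or technical genes, and 18 genes whatever their result. It named 53 genes, of which 1 is not reported here. Lists with at least 3 listed members were tested against the other listed genes, 1133 in all, with limma's camera at a preset correlation of 0.01, and as an alternative with an estimated correlation, adjusted over the 8 lists tested. As a further alternative, fry tested each list against no change, without comparing it with other genes.

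The tests were checked on simulated data of the same 45037 probe sets, with 200 brighter ones changed. Of 50 simulated changes each of log2 size 1, 2, 3 and 4, limma recovered 0%, 10%, 16% and 44%, and it called 5 unchanged probe sets. Most simulated changes of these sizes were therefore missed with 2 arrays against 2. The camera test called a simulated list that was shifted and did not call an unshifted list.

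Alternatives were quantile normalization, median centring, the brighter probe sets only, log2 of the intensity plus 16, no variance trend, the replicate number as a block, each array left out, a minimum log2 difference of 1, a fold rule with no test and the mean over a gene's probe sets. Scaling to 18 hybridization control probe sets, testing the authors' list alone and testing only probe sets above the highest Bacillus subtilis control were added after the data were seen. Counts of Gene Ontology terms and shuffles were made in Python 3.11.15 with scipy 1.17.1.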

Results

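The nail matrix is the epithelium at the root of the nail whose cells multiply, move forward and harden into the nail plate. Its proximal part lies deep under the nail fold and its distal part lies closer to the nail bed. Both parts were dissected from mice aged 8 weeks, and their total RNA was hybridised to Affymetrix expression arrays, 2 for the distal and 2 for the proximal matrix. The comparison asks which genes separate the distal matrix from the proximal matrix. Each array gave intensities for 45037 probe sets (groups of short oligonucleotides that read a transcript) besides 64 control probe sets. Median intensities were 45.2 and 48.4 on the distal arrays and 55.7 and 41.6 on the proximal arrays. The number of arrays, 2 per region, limits the precision of every value below.

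Krt42, a type I keratin gene, was 10.3-fold higher in the distal matrix, with intensities of 8877 and 12310 on the distal arrays and 731 and 1415 on the proximal arrays. Genes of keratin-associated proteins, the small proteins that bind keratin filaments to each other in hair and nail, had higher intensities in the distal matrix, all 8 of those that could be named, and 3 of them passed the test. Krt1, a keratin of the suprabasal epidermis, was 2.36-fold higher. Expi (now Wfdc18), a gene of a secreted protein of the whey acidic protein family, was 14.9-fold higher (log2 difference 3.90, and 2.94 and 4.86 without proximal replicate 1 and 2), and Olah, whose enzyme releases medium-chain fatty acids, was at least 8.41-fold higher because its proximal intensities of 4.8 and 17.7 were not above the control background. The intensity of Expi on proximal replicate 1, 44.8, was below the highest Bacillus subtilis control of that array (96.8). On the proximal side, the 4.86 rests on that intensity alone.

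All of these except 5 of the keratin-associated protein genes passed the test. The log2 difference of Krt42 (Entrez gene 68239), distal minus proximal, was 3.36 ± 0.29 (SE, n = 2 arrays per region; limma, Benjamini-Hochberg adjusted p = 8.02e-08), and its second listed probe set had a difference of 2.23 (limma, adjusted p = 0.0152). The difference was 3.90 ± 0.57 for Expi (limma, adjusted p = 0.00146), 5.92 ± 1.06 for Olah (limma, adjusted p = 0.0155) and 1.24 ± 0.24 for Krt1 (limma, adjusted p = 0.0429). The keratin-associated genes that passed were Krtap16-8 (now Krtap6-5) at 3.11 ± 0.57, Krtap6-2 at 2.34 ± 0.43 and Krtap16-7 (now Krtap21-1) at 2.19 ± 0.38, with limma adjusted p-values of 0.0195, 0.0201 and 0.0146. The intensity of Krtap16-8 on proximal replicate 1, 94.6, was below the highest Bacillus subtilis control of that array (96.8). Krtap8-1 (2.21), Krtap9-3 (2.37) and 1110032D16Rik (now Krtap22-2, 1.62) did not pass over all probe sets. Nor did the representative probe sets of Krtap6-1 and Krtap6-3, which were not above background on the proximal arrays and at least 4.45-fold and 3.64-fold higher on the distal ones. Without distal replicate 2 the bound of Krtap6-3 was 1.46-fold, and without proximal replicate 1 the difference of Krtap9-3 was 1.30. The call of Expi ended without proximal replicate 1 (2.94; limma, adjusted p = 0.229), and that of Krtap16-7 without proximal replicate 2 (1.49; limma, adjusted p = 0.970). A probe set that the authors' list assigns to Krtap6-1 together with another gene, singled out after its value was seen, passed with a difference of 3.15 (limma, adjusted p = 0.000918), and fell short without proximal replicate 1 (2.49; limma, adjusted p = 0.273). The call of Krt42 ended when arrays were scaled to hybridization controls (limma, adjusted p = 0.0504), and that of Olah under quantile normalization (0.0559). The calls of Krt1, Krtap16-8, Krtap6-2 and Krtap16-7 ended under quantile normalization, median centring and hybridization control scaling alike, with limma adjusted p-values from 0.0517 for Krtap16-8 to 0.875 for Krt1.

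As a group, the 8 keratin-associated protein genes had a median log2 difference of 2.36, or 2.20 with Krtap6-1 and Krtap6-3 at their bounds, and stood apart from the other listed genes (camera, adjusted p = 1.51e-07). This call was lost with the correlation between genes taken from the data (adjusted p = 0.224 with an estimated correlation). Adjusted over the list alone, 8 of the 8 passed. All 8 could be named only because the authors had chosen their probe sets for fold change on these same arrays, so neither count is independent evidence of the direction. All 8 were higher in the distal matrix under each of the scalings tried. Members of this family are much alike in sequence, so a probe set can read transcripts of more than its own gene.

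Several genes with no role specific to nail were also higher in the distal matrix. Hsph1, a heat shock protein gene, was higher by 2.85-fold and Unc45a, a gene of a myosin chaperone, by 4.37-fold. Klhdc2 and Dcun1d1, which encode parts of the ubiquitin and neddylation machinery, were higher by 3.49-fold and 4.07-fold, and the uncharacterised B230354K17Rik by 4.73-fold. Their limma adjusted p-values lay between 0.00934 for Hsph1 and Klhdc2 and 0.0356 for Dcun1d1. Under each other scaling the calls of Hsph1, Klhdc2, Unc45a and Dcun1d1 ended (adjusted p from 0.0517 for Klhdc2 to 0.836 for Hsph1), and that of B230354K17Rik ended under median centring (0.0851) and hybridization control scaling (0.791). The other named genes that passed, singled out after their values were seen, were Pctk1 (now Cdk16), Tfpt and Dvl1, with log2 differences of 1.51, 1.56 and 1.32. All 3 fell short without proximal replicate 1 or 2, and the difference of Pctk1 was 0.86 without distal replicate 2. Another probe set of Tfpt was 2.06-fold higher in proximal matrix in the authors' deposited table. Dvl1 encodes a cytoplasmic relay of Wnt signals (limma, adjusted p = 0.0431).

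**Figure D1:**
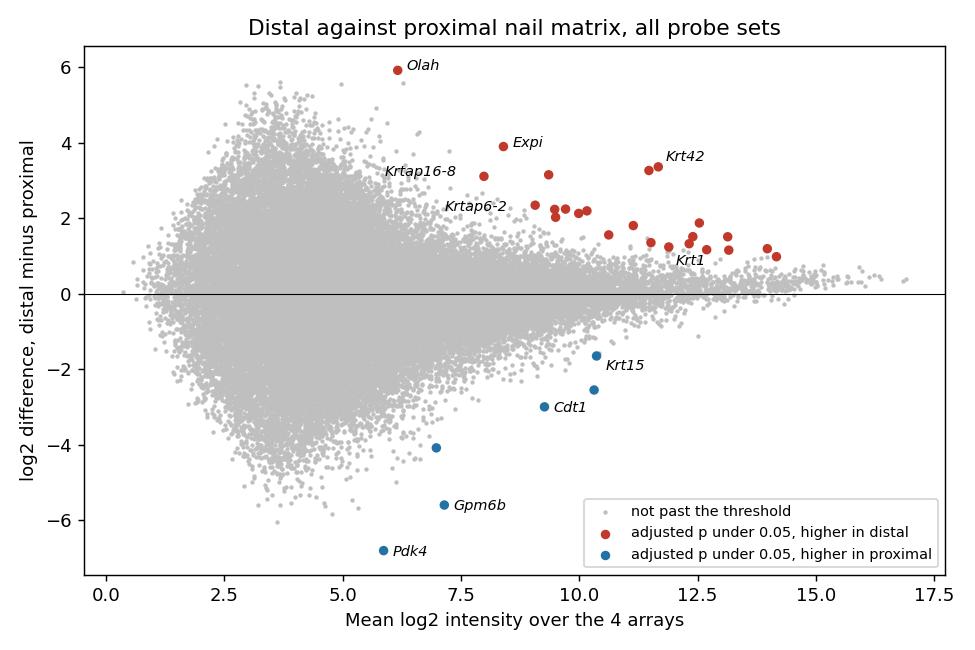
The log2 difference between distal and proximal matrix (vertical axis) is plotted against the mean log2 intensity over the 4 arrays (horizontal axis), a point per probe set. Coloured points are the 24 probe sets called higher in distal matrix (red) and the 6 called higher in proximal matrix (blue), and differences of dim probe sets spread more widely than those of bright ones.

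The proximal matrix held more RNA of Krt15, Gpm6b, Pdk4 and Cdt1, the named genes that passed in that direction. Krt15, a keratin gene of basal cells that also marks stem cells of the hair follicle, was 3.14-fold higher, with intensities of 2306 and 2372 against 612 and 907. Gpm6b, a membrane protein gene known from nervous tissue, was at least 14.4-fold higher, and Pdk4, whose kinase turns off pyruvate dehydrogenase, at least 9.0-fold. Neither Gpm6b nor Pdk4 was above the control background on the distal arrays. Cdt1, which licenses DNA for replication, was 7.99-fold higher, but its proximal intensities of 665 and 4553 differed from each other almost as much as the regions did.

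The log2 differences, distal minus proximal, were -1.65 ± 0.33 for Krt15, -5.60 ± 0.80 for Gpm6b, -6.81 ± 1.17 for Pdk4 and -3.0 ± 0.60 for Cdt1 (SE, n = 2 arrays per region), with limma adjusted p-values of 0.0430, 0.00119, 0.0118 and 0.0430. The call of Krt15 ended under quantile normalization (limma, adjusted p = 0.0561), median centring (adjusted p = 0.544) and scaling to hybridization controls (adjusted p = 0.471), and that of Cdt1 under quantile normalization (0.141) and median centring (0.112), all with the same direction. The difference of Cdt1 was -4.39 without proximal replicate 1 and -1.61 without proximal replicate 2, where its call also ended (0.970). The genes next in order of p did not pass, among them Tpm3 (-1.89), Itga8 (-4.39), Krt2 (-2.02), the fibroblast gene Dcn (-1.89) and Spink12 (-1.82), with limma adjusted p-values from 0.0674 for Tpm3 to 0.125 for Dcn and Spink12. The proximal intensity of Itga8, an integrin gene of mesenchymal cells, was at least 6.10-fold above the distal one.

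Among genes of the Wnt pathway, Wnt5a, the ligand gene, had intensities 3.87-fold higher in the distal matrix, while Lef1 and Tcf7, the transcription factor genes through which beta-catenin acts, had higher intensities in the proximal matrix, by 5.61-fold and 1.86-fold. None of these passed. The log2 differences were 1.95 ± 0.57 for Wnt5a, -2.49 ± 0.76 for Lef1 and -0.89 ± 0.68 for Tcf7 (limma, adjusted p = 0.523, 0.606 and 0.905), with Wnt5a at 1.30 without proximal replicate 2 and Lef1 at -1.83 without distal replicate 2. In the authors' deposited table Wnt5a was 4.59-fold higher in distal matrix, and Lef1 and Tcf7 were 4.39-fold and 2.04-fold higher in proximal matrix. Of the 4 listed Wnt target genes, 3 were higher in proximal matrix (Lef1, Tcf7 and Tnfrsf19 at -1.25) and 1 in distal matrix (Apcdd1 at 0.67), 0 passed and 1 passed adjusted over the list alone. Apcdd1 was at 0.04 without distal replicate 1, and its other probe sets were higher in distal matrix by a log2 difference of 1.38 and by at least 3.76-fold. The group did not stand apart (camera, adjusted p = 0.752). Among receptors only Ryk (-1.21) was listed, and among secreted inhibitors only Sfrp1 (-2.24), neither of which passed. The difference of Sfrp1 was -0.51 without distal replicate 1, and that of Ryk -0.71 without distal replicate 2. Wnt5a, Ryk and Sfrp1 were each the only listed member of their lists, where adjusted over the list alone is the unadjusted p, under 0.05 for Wnt5a and Sfrp1.

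Of 9 listed genes of basal, suprabasal and nail bed keratinocytes, Krt15 passed as higher in the proximal and Krt1 as higher in the distal matrix. The intensities of 8 of the 9 were higher in the proximal matrix, as were those of 68.3% of all listed genes, and no group stood apart from the others. In the basal group Plec1 (-0.92, and -0.40 without proximal replicate 1) did not pass, nor did Itgb4, whose -2.0 came from distal replicate 1 and was -0.04 without it, in the suprabasal group neither Krt2 (-1.17 without distal replicate 1) nor Lor (-4.16, and -2.26 without distal replicate 2) did, and of the nail bed group Krt17 (-1.0), Krt6a (-0.87) and Krt6b (-0.21) did not. Adjusted over each list alone, 1, 3 and 1 genes passed in these groups, and the camera adjusted p-values were 0.480, 0.830 and 0.605. The direction of Krt6b turned when distal replicate 2 or proximal replicate 2 was left out, to 0.20 and 0.65.

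Of 3 listed skin stem cell markers, Krt15, Id2 (-1.11) and 1600029D21Rik (now Plet1, -1.33, and -0.46 without distal replicate 2), all were higher in the proximal matrix, 1 passed, and 2 passed adjusted over the list alone (camera, adjusted p = 0.340). Of 6 listed cell cycle genes, Cdt1 passed. Bub1 (-2.46), Rrm1 (-1.40) and Mcm7 (-0.73) were higher in the proximal matrix and Ccne1 (1.71) and Mcm2 (1.18) in the distal matrix without passing, and 3 of the 6 passed adjusted over the list alone (camera, adjusted p = 0.830). Without distal replicate 2 the differences were -1.21 for Bub1, -0.79 for Rrm1 and -0.22 for Mcm7, and without proximal replicate 1 they were 0.99 for Ccne1 and 0.51 for Mcm2. Hoxc13, a homeobox gene needed for hair and nail formation, had a log2 difference of -2.01 ± 0.57 (limma, adjusted p = 0.444), and the authors' deposited table has it 3.37-fold higher in proximal matrix. Selenbp1 (-1.87), the other listed gene of hair and nail differentiation, and En1 (1.69), listed with Hoxc13 as a patterning gene of the limb, did not pass. They were at -0.81 and 0.86 without proximal replicate 2. Nor did Bmpr1a (-1.05), which was listed with Id2 for BMP signalling, or Spred1 (0.92) and Spred2 (-0.87, and -0.58 without distal replicate 2), listed for FGF signalling. The sign of Spred1 turned as the mean of its probe sets (-0.46). Adjusted over the list alone, 1 gene passed in each of the hair and nail differentiation, BMP and FGF lists and 2 in the patterning list.

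**Figure D2:**
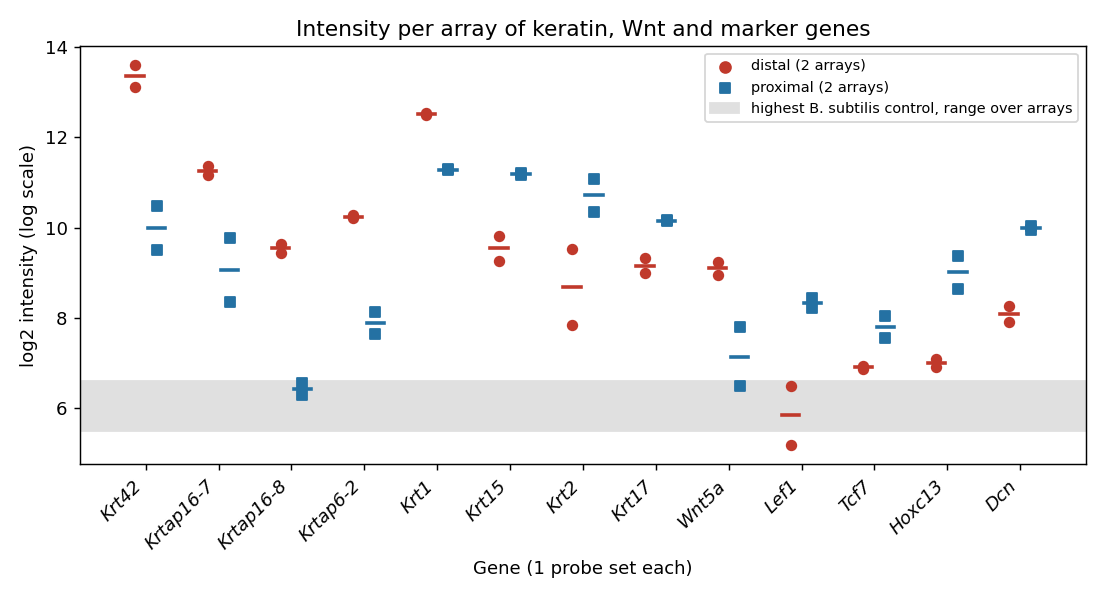
Log2 intensity of 13 genes on each array (vertical axis, log scale), with 2 distal arrays (circles) and 2 proximal arrays (squares) per gene and a line at each group's mean. The grey band is the range over arrays of the highest control probe set for Bacillus subtilis genes, and Lef1 lay within or below it on the distal arrays. Krtap16-8 lay within it on the proximal arrays, and Wnt5a on proximal replicate 2. The keratin-associated genes and Krt42 sit higher on the distal arrays and Krt15 on the proximal arrays.

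Of the marker lists of other cell types, a single gene was in the authors' list: Dcn, a gene of dermal fibroblasts, with intensities 3.71-fold higher in proximal matrix (limma, adjusted p = 0.125, not passed). For endothelial and mural, immune, pigment, Schwann, bone, muscle, fat, blood, and Merkel or simple epithelial cells, for the inner root sheath, for hard keratins and for hedgehog and Notch signalling, 0 genes of the lists fixed beforehand were in the authors' list, so their intensities could not be named here. Of the nerve guidance genes, Sema5a was listed, and its log2 difference of 4.03 came from 1 distal array at 381, with the other distal array at 2.8. It did not pass. Its proximal intensities of 2.5 and 1.6 were not above the control background, and no bound on its fold could be given. Of the early response and heat shock genes, Hsph1 passed in the distal direction and Cyr61 (now Ccn1) did not (1.44; limma, adjusted p = 0.365), while both other probe sets of Cyr61 had the opposite sign. The 3 listed ribosomal protein genes, Rps6 (-1.49), Rpl9 (-1.22) and Rps25 (-0.90), did not pass (camera, adjusted p = 0.573), also with 0 adjusted over the list alone, and without distal replicate 1 Rps6 was at -0.47 and Rpl9 at -0.64.

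In all, limma called 30 of 45037 probe sets, 24 higher in distal and 6 higher in proximal matrix, at a Benjamini-Hochberg adjusted p under 0.05. Of these, 19 distinct named genes were identified and 10 probe sets had no single gene name. Of the 30 called, 24 lay among the brightest 10% of probe sets, a count separate from the 24 higher in distal matrix. At an unadjusted p under 0.05 there were 2294 probe sets, where 2252 would come by chance. The groups did not overlap for 15649 probe sets, 34.7% against 33.3% by chance. The correlation across probe sets was 0.669 between the distal arrays, 0.721 between the proximal arrays and 0.662 to 0.721 between arrays of different regions, so the distal arrays were less alike than most pairs of arrays across regions. Among the brightest 10% of probe sets it was 0.882 between the distal arrays, below the 0.901 to 0.905 of every pair across regions, and 0.952 between the proximal arrays. Probe sets are not independent replicates.

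The count depended on the settings: limma called 9 (6 distal, 3 proximal) under quantile normalization, 12 (3 distal, 9 proximal) when arrays were scaled to the hybridization controls, and 0 without a trend of variance with intensity, where 3010 had an unadjusted p under 0.05. Leaving out distal replicate 1 gave 899 (306 distal, 593 proximal), leaving out distal replicate 2 gave 635 (233 distal, 402 proximal), and leaving out proximal replicate 1 or 2 gave 4 or 7. Of the 16 genes that passed and were named by the rule fixed beforehand, Expi, Gpm6b and Pdk4 passed under each scaling tried, 15 fell short when proximal replicate 1 or proximal replicate 2 was left out, with Krt42 alone passing both times. Of the 16, Krt42 alone passed among the brighter probe sets and none passed without the variance trend, while none changed direction under any alternative. The called probe set with the smallest p has no gene name and was 9.61-fold higher in distal matrix (limma, adjusted p = 4.76e-08). Its log2 difference was 3.26, and 3.11 to 3.42 with an array left out.

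The authors' deposited table lists 1435 probe sets for genes, 1010 of them higher in proximal and 425 higher in distal matrix, with folds of 1.99 to 17.3 and no adjusted test. In the intensities, 1415 of them had the same direction, 684 an unadjusted p under 0.05 and 23 an adjusted p under 0.05 by limma. In it 70.4% were higher in proximal matrix, whereas 80% of the probe sets called over the whole array were higher in distal matrix. Tested on that table alone, limma called 273, of which 89 were higher in distal and 184 in proximal matrix. The listed probe sets had been kept for their fold on these same arrays, so these counts and the shared direction are not independent evidence.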

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

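Scaling to the hybridization controls, testing the authors' list alone and testing probe sets above the highest Bacillus subtilis control were chosen after the results were seen. The 30 called probe sets became 9 under quantile normalization, 8 under median centring, 17 with log2(value + 16), 12 with hybridization control scaling and 2 among the brighter probe sets, of which 8, 8, 17, 7 and 2 were among the 30. They became 2 above the highest Bacillus subtilis control, 273 within the authors' list alone, where fewer tests and probe sets chosen for fold were entered, 29 with a log2 difference of at least 1, 11118 by fold and lack of overlap with no test, and 0 without a variance trend, where limma gave 3010 at an unadjusted p under 0.05. Leaving out an array gave 4 to 899: 899 and 635 without distal replicate 1 or 2 (34.0% and 36.7% distal), where the spread came from the proximal arrays alone, and 4 and 7 without proximal replicate 1 or 2, where it came from the less similar distal arrays. The lone array was assumed to vary like the other region. With the replicate block 90 probe sets were called, all 30 among them. Same-numbered arrays did not deviate together over all probe sets (correlation -0.0072). With 2 arrays per region this cannot tell whether equal numbers mark the same animals or day, so pairing stays open. Hybridization control scaling moved the median log2 difference of all probe sets from -0.06 to -0.57, and the split from 24 distal and 6 proximal to 3 and 9. With an estimated correlation 0 gene lists passed, and 1, the keratin-associated proteins, under every other camera alternative (adjusted p from 4.77e-09 to 2.44e-05); fry, which tests the list against no change, gave 0.0367. Among the named genes, 501 alternative values kept direction and side of the threshold, 95 fell short of it, 35 passed it, and 4 changed sign: Cyr61 (-0.66) and Spred1 (-0.46) as the mean of their probe sets, and Krt6b without distal replicate 2 (0.20) or proximal replicate 2 (0.65), with -1.07 to 0.65 over the left-out arrays. The cell cycle list turned direction without a variance trend (adjusted p = 0.960). Except where stated, the cause was not tested. Dim signal is a limit, since 33.6% to 47.5% of probe sets lay above the controls.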

Other observations

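The tests on hybridization control scaling, the brightest probe sets after median centring, keratinocyte genes, opposite probe sets and Gene Ontology terms were chosen after the results were seen. No Gene Ontology term set the listed genes of a region apart from the rest: the smallest adjusted p over 166 terms, by Fisher's exact test against the share of annotated genes higher in proximal matrix (530 against 236 with a process term), was 0.287. Of 26 listed genes annotated to RNA splicing, 24 were higher in proximal and 2 in distal matrix, among them Snrpd3, a core spliceosome protein gene (3.82-fold in the authors' deposited table), Khsrp (3.35-fold) and Rbm39 (2.92-fold). Of 11 genes of anterior/posterior pattern formation, 11 were higher in proximal matrix. Of the genes of the intermediate filament 10 were higher in distal and 5 in proximal matrix, 8 of the 10 being Krtap genes or Krt42, described already. Of the genes integral to the plasma membrane, 7 were higher in distal and 2 (Tm4sf1 and Osmr) in proximal matrix. Among the 7 were P2rx7, an ATP-gated channel gene (6.69-fold in the authors' deposited table), and Boc, a hedgehog co-receptor gene (3.22-fold).

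Most called probe sets, 24 of 30, were higher in distal matrix, but most were higher in proximal matrix when distal replicate 1 or 2 was left out (34.0% and 36.7% distal). The median log2 difference of the probe sets called higher in distal matrix was 1.95. A scaling that lifted all bright probe sets of the distal arrays by about 1.95 is argued against. The median of the brightest 5% was 0.121 (median absolute deviation 0.224), held near 0 in part by the authors' scaling. After median centring, which does not rest on bright probe sets, it was 0.162 (-0.07 to 0.40 with an array left out). Of the brightest 5%, 64.2% were higher in distal matrix, so a smaller shift of bright probe sets is not argued against. The choice of scaling stays open: the share of calls higher in distal matrix was 66.7% under quantile normalization, 75% under median centring and 25% with hybridization control scaling, which by construction moved every difference by the same -0.51. Among the 3 splits of the 4 arrays, 1 gave as many calls, the real one with 30, and the highest other gave 0, but 3 splits are too few for a share under 0.05. A biological cause in the regions stays open, and no test here separates it from the scaling.

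The 8 listed keratin-associated protein genes were higher in distal matrix, by a median log2 difference of 2.36, where that of all 1133 listed genes was -0.94. A lower share of epithelium in the proximal pieces would lower all keratinocyte genes there, but relative to the listed genes the median of 9 listed keratinocyte genes was -0.064, with a median absolute deviation of 0.79, against 3.29 for the keratin-associated genes. This median cannot decide the question, since the 9 genes were listed only for their fold on these arrays. Keratinocyte genes outside the authors' list were not examined. While 8 of the 9 were higher in proximal matrix, Krt42, a keratin gene outside the 9, was higher in distal matrix (3.36), which goes with a lower share of epithelium. Dcn, a fibroblast gene, had a difference of -1.89 and Itga8, a gene of mesenchymal cells, was at least 6.10-fold higher in proximal matrix, which also go with it. They are weak evidence, since neither gene passed and Itga8 was named for its small p-value. Dcn was the only listed gene of 20 dermal fibroblast genes, and the intensities of the others were not examined. The 8 differences did not vary beyond their standard errors (heterogeneity p = 0.856, an approximate chi-square test), so a single abundant transcript read by several probe sets and a joint difference of the genes cannot be told apart without the probe sequences. No test here separates a biological cause in the regions from a shared transcript or a lower share of epithelium in the proximal pieces.

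Listed probe sets of a gene sometimes disagreed. Of 87 genes with several listed probe sets, 20 (23.0%) had them in opposite directions, among them Fbxl20, with folds of 6.62 in proximal and 4.62 in distal matrix in the authors' deposited table, and Spred1. If listed directions were unrelated to the gene, 33.6 such genes would be found on average (27 to 40 in 95% of 10000 shuffles; one-sided permutation p = 0.0005), so they are related, but not in every gene. Whether noise in dim probe sets or differing transcripts made the 20 was not tested.

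Eif2s3y, a gene of the Y chromosome, had intensities of 62.3 and 66.7 on the distal and 383 and 358 on the proximal arrays (log2 difference -2.52; limma, adjusted p = 0.404). The distal intensities were close to the highest Bacillus subtilis control of those arrays (58.0 and 81.0). Eif2s3y was the only listed gene of 5 sex-linked ones. The rest did not enter the authors' list, which had a fold cut-off of 1.99 and no effective limit on p. A difference in sex between the regions would be expected to move them too, so their absence goes against it. Their intensities could not be named, so whether the animals of the regions differed in sex was not tested directly.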
